A study of Mus musculus with 12 samples.

How the data were processed

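The deposited values are log2 expression per probe set for 12 single-colour Affymetrix mouse arrays, made by the authors with RMA (robust multi-array average), per the submitters' processing notes; the version is not given in the sources used here. The log base was not stated and was taken from the values, which ran from 2.14 to 14.94 with nearly equal quartiles on every array. Per the labels, KSL cells were cultured with IL-6 (20 ng/ml), IL-11 (10 ng/ml), Flt3 ligand (50 ng/ml) and stem cell factor (10 ng/ml) in 10% serum, with or without TNF at 10 ng/ml for 24 h, and 5 to 15 ng of total RNA was amplified for each array. Groups and replicate numbers came from the sample labels, and every array was used.

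The platform annotation gave 1 gene symbol to 34958 of 45101 probe sets, several symbols to 932, and did not list 9211, which are unnamed here; 64 control probe sets were left out. A gene was represented by the probe set with 1 symbol that had the highest mean over all arrays, which gave 18193 genes, 9010 of them with several probe sets. Gene order came from the GRCm38.p6 annotation, in which 18145 of the genes had a position, and no coordinates are given. RMA already corrects background and equalises array distributions, so an overall shift between groups could not be seen, and genes near the floor have compressed fold changes. The number of arrays limits the precision.

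Before the data were examined, the groups, tests, 31 gene lists (681 genes, 613 measured, 0 in more than 1 list), alternatives and rule for named genes were fixed. Each gene was fitted with limma 3.58.1 in R 4.3.3, with 1 mean per group over all 12 arrays and empirical Bayes moderation, and 7 contrasts were tested, 2-sided, with Benjamini-Hochberg adjustment and an adjusted p under 0.05 as the threshold. The contrasts were TNF in each genotype, genotype at each treatment, their interaction, and the averages of both effects. Gene lists with at least 5 measured genes were tested with camera at a preset correlation of 0.01, and also with an estimated correlation and with fry; the sex-linked list was too short. fry tests whether a list moves on balance in 1 direction, without comparison to other genes. Genes named in the text were the 10 highest and 10 lowest log2 fold changes among calls whose arrays did not overlap between groups, or the 5 highest and 5 lowest for the interaction and the averages, filled up to 5 by unadjusted p where calls were fewer and then stated as not passing. For a gene list they were its called members or those with the smallest p. Fancc was always named, and predicted genes were skipped. 6720489N17Rik, Aopep, Ptch1, Tm4sf1, single probe sets, unnamed probe sets and the sex-linked transcripts Xist and Eif2s3y were named after their values were seen.

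The scripts were tested on simulated data with 18193 genes, of which 100 were changed by 1 and 100 by 2 on the log2 scale. Of these, 84% and 97% were recovered for TNF in wild type, 87% and 98% for TNF on the arrays labelled mutant, 83% and 99% for genotype without TNF, 81% and 97% for genotype with TNF, 68% and 92% for the interaction, 97% and 99% for the TNF average, and 94% and 100% for the genotype average. In the same order 11, 8, 12, 16, 8, 5 and 17 unchanged genes were called. A simulated shift of 0.5 in the p53 target list was recovered for TNF in wild type with 0 of the other lists called. Simulated genes varied independently of each other, so neither correlated genes nor an outlying array was imitated.

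The alternatives were a replicate block, a filter that kept the 9444 genes with at least 3 values above the median of all values (7.44), the mean of a gene's probe sets, centring on array medians, cyclic loess, trended and robust moderation, array weights (statmod 1.5.0), a fit of only the groups compared, a 2-fold minimum, and leaving out each array. Chosen after the data were seen were tests of all 45037 probe sets that are not controls, Xist and Eif2s3y levels as covariates, and only the 7 arrays with signal from both Xist and Y-linked genes.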

Results

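Expression was measured in KSL cells, the c-Kit-positive, Sca-1-positive, lineage-negative fraction of mouse bone marrow that holds haematopoietic stem and early progenitor cells. The cells came from wild-type mice and from mice deficient in Fancc, aged 2 to 4 months, and were cultured for 24 h in serum with IL-6, IL-11, Flt3 ligand and stem cell factor. Tumour necrosis factor alpha (TNF), an inflammatory cytokine, was added at 10 ng/ml to the treated cultures. The 12 arrays formed 4 groups of 3, untreated and TNF-treated cells of each genotype. The design asked what TNF changed in each genotype, how the genotypes differed, and whether the response to TNF depended on genotype. The number of arrays limits the precision. The labels did not say that the replicates came from separate mice, so p-values measure the spread between these samples, which may in part be technical. Sex-linked transcripts, given below, differed between replicates in every group but the treated arrays labelled mutant. Replicates of those groups therefore did not all come from the same mice.

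Fancc encodes a subunit of the Fanconi anaemia core complex, which acts in the repair of DNA crosslinks. Its signal was not lower on the arrays labelled mutant. The brightest of its 3 probe sets read 8.28, 8.22 and 8.49 on the untreated wild-type arrays and 8.40, 8.65 and 8.22 on the TNF-treated ones (log2). It read 9.16, 8.73 and 9.15 on the untreated arrays labelled mutant and 8.87, 9.12 and 8.95 on the treated ones. Averaged over treatment the arrays labelled mutant stood 0.62 higher on the log2 scale (SE 0.10, 12 arrays), which did not pass over all genes (limma adjusted p = 0.137). The other probe sets stood 0.30 and 0.49 higher, and neither passed. Whether these probe sets lie in the disrupted part of the gene is not known here, and a probe set outside that part checks nothing. Genotype is therefore given below as labelled. Fancc itself did not pass for TNF, with a log2 change of 0.09 in wild type and -0.03 on the arrays labelled mutant.

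**Figure D1:**
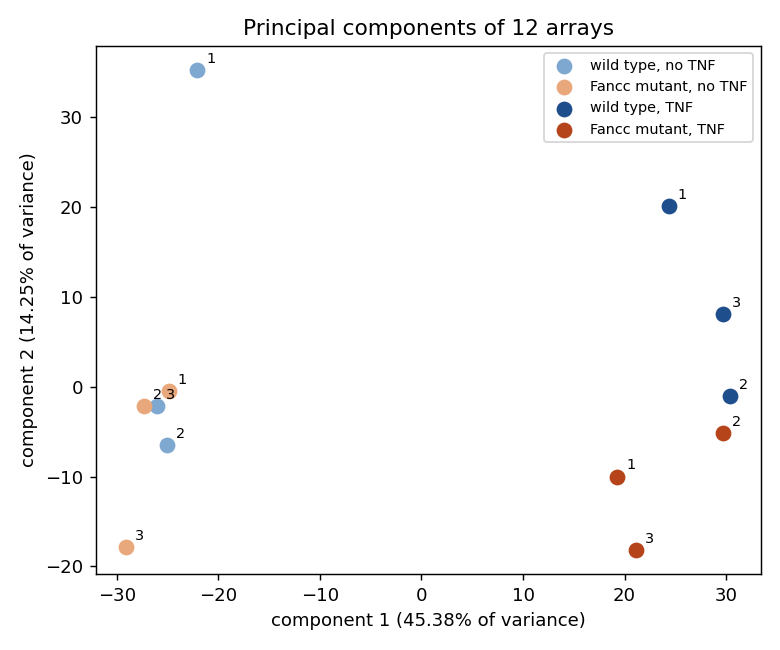
Scores of the 12 arrays on the first principal components of the gene table, which hold 45.38% (horizontal axis) and 14.25% (vertical axis) of the variance. Points are arrays, numbers are replicate numbers and colours are groups; TNF-treated and untreated arrays lie apart on the horizontal axis, and untreated wild-type replicate 1 lies highest on the vertical axis, at 35.3.

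In wild-type cells TNF raised Aoc1, a diamine oxidase gene, by 6.07 on the log2 scale (67.4-fold, SE 0.22, 3 arrays per group). Acod1, whose product makes itaconate in activated macrophages, rose by 5.33 (SE 0.46), and Dpysl3 rose by 4.98 (SE 0.26). Aoc1, Acod1 and Dpysl3 read at most 4.7 on the untreated wild-type arrays, near the floor, where fold changes are compressed. Mmp8, the neutrophil collagenase, fell by 5.08 (SE 0.47), and F13a1, the A subunit of coagulation factor XIII, fell by 4.62 (SE 0.48). Among the other genes with the highest rises were the receptors Gpr25 (4.60), Fpr2 (4.25) and Gpr84 (3.86), the granzyme gene Gzmc (4.00), ceruloplasmin Cp (3.97), Ly6i (3.91) and Sema6d (3.89). Ifitm6 (-4.13), the neutrophil elastase gene Elane (-3.58), Ngp (-3.29), Vcan (-3.23), Mgam (-3.21), the chemokine receptor gene Ccr1 (-3.11) and Sirpb1a (-3.10) fell, as did Chil3 (-4.62, SE 1.01). Of 18193 genes, 489 rose and 424 fell (913 in all, limma, adjusted p under 0.05), and 384 of these differed at least 2-fold. The split was 457 higher and 529 lower with arrays centred on their median and 556 and 392 with cyclic loess. The 3 arrays of each group did not overlap for 20.6% of genes, against 10% by chance. Only 523 genes were called when just these 2 groups were fitted, 509 without untreated replicate 3, 474 without treated replicate 3, and 410 with the Xist and Eif2s3y levels as covariates. Chil3 (adjusted p = 0.0254) and Elane (adjusted p = 0.0241) did not pass with those covariates (adjusted p = 0.0866 and 0.108), nor did Chil3 without untreated replicate 1, 2 or 3 or treated replicate 1 or 2 (adjusted p from 0.0652 to 0.0868), or Elane without replicate 2 or 3 of either group (from 0.0737 to 0.0987).

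NF-kB targets were the gene group with the clearest rise. Of 30 measured members, 16 rose and 0 fell with TNF in wild type, and 21 rose when adjusted over the list alone. Relb and Nfkb2, subunits of the alternative NF-kB dimer, rose by 3.20 (SE 0.12) and 1.97 (SE 0.12), and the pathway inhibitors Tnfaip3 and Nfkbia by 3.51 (SE 0.16) and 1.49 (SE 0.09). The list passed camera at adjusted p = 5.27e-25, and also with an estimated correlation (adjusted p = 0.000305 with an estimated correlation). MHC class II genes rose in 5 of 9 cases, the same number as when adjusted over the list alone, where 2 others fell. Cd74, the invariant chain, rose by 2.55 (SE 0.27), H2-Eb1 by 2.40 (SE 0.30), H2-Aa by 2.06 (SE 0.22) and the class II transactivator Ciita by 1.42 (SE 0.34). This list passed camera at adjusted p = 0.00046 but not with the correlation taken from the data (adjusted p = 0.428 with an estimated correlation). Interferon-stimulated genes rose in 6 of 30 cases, with 9 risen and 1 fallen when adjusted over the list alone. Ifih1, a sensor of viral RNA, rose by 1.11 (SE 0.20) and Usp18 by 0.87 (SE 0.20). Camera gave adjusted p = 0.000484 for this list (adjusted p = 0.208 with an estimated correlation). Over the 19 alternatives of each list the adjusted p ran from 1.16e-26 to 0.000305 for NF-kB targets, from 8.58e-06 to 0.428 for MHC class II genes and from 6.42e-05 to 0.208 for interferon-stimulated genes.

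Of 24 granulocyte markers, 11 fell and 0 rose with TNF in wild type, and 19 fell and 1 rose when adjusted over the list alone. The chemokine receptor gene Cxcr2 fell by 2.62 (SE 0.19), the lactoferrin gene Ltf by 2.77 (SE 0.34) and S100a8 by 2.93 (SE 0.42), with camera adjusted p = 2.94e-12 for the list (adjusted p = 0.208 with an estimated correlation). Of 23 monocyte, macrophage and dendritic markers, 9 fell and 1 rose, and 11 fell and 1 rose when adjusted over the list alone. Irf8, a transcription factor of the monocyte lineage, fell by 1.78 (SE 0.22) and Ccr2 by 2.00 (SE 0.26), while the fractalkine receptor gene Cx3cr1 rose by 1.80 (SE 0.37). Camera gave adjusted p = 0.000302 for this list (adjusted p = 0.563 with an estimated correlation). Of 15 mast cell, basophil and eosinophil markers, 3 fell, namely Mcpt8 (-2.15), the histidine decarboxylase gene Hdc (-2.05) and Il4 (-0.62), and 4 fell when adjusted over the list alone. This list gave camera adjusted p = 0.00176 (adjusted p = 0.428 with an estimated correlation). Unfolded protein response genes Atf6 (-0.64) and Xbp1 (-0.62) fell, 2 of 22 members and 4 when adjusted over the list alone, with camera adjusted p = 0.0236 (adjusted p = 0.208 with an estimated correlation). The mast cell list did not pass without untreated replicate 2 (adjusted p = 0.0612), nor the unfolded protein list without untreated replicate 3 (0.141) or treated replicate 1 (0.0887). Over 19 alternatives the adjusted p ran from 9e-15 to 0.208 for granulocyte markers, from 1.14e-05 to 0.563 for monocyte, macrophage and dendritic markers, from 0.000571 to 0.428 for the mast cell list and from 0.00251 to 0.208 for the unfolded protein list. Sex-linked transcripts differed between arrays of these groups. Xist read 5.47 and 5.06 on untreated wild-type replicates 1 and 2 and 12.53 on replicate 3, against 12.52, 12.47 and 13.08 on the treated wild-type arrays, while the Y-linked Eif2s3y read 3.79 on treated replicate 3 and 11.25 and 11.16 on the other treated wild-type arrays.

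**Figure D2:**
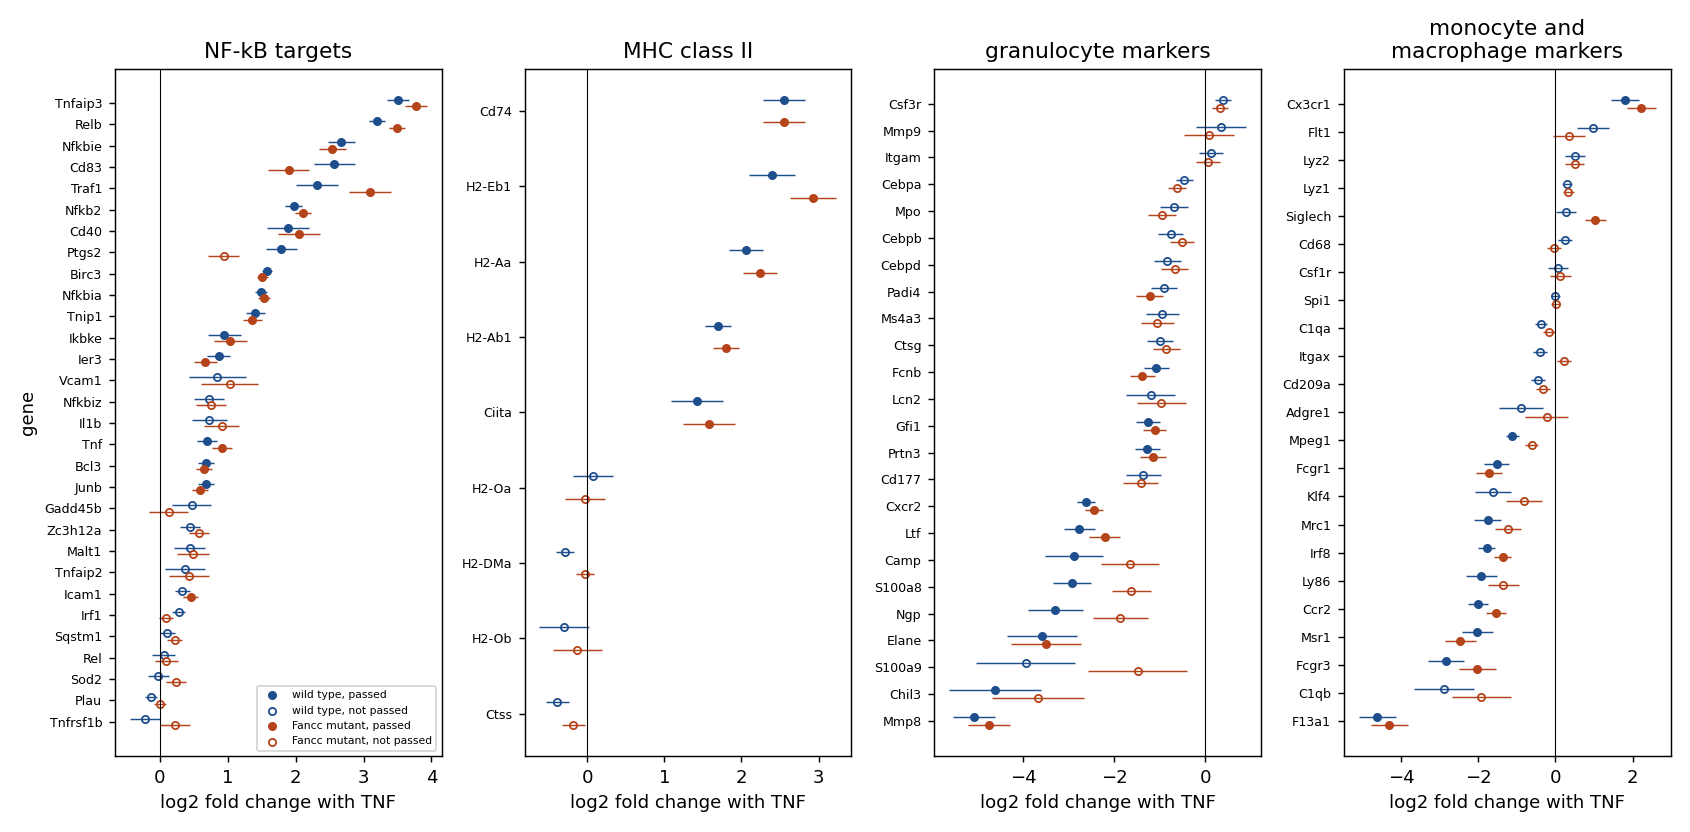
Log2 fold change with TNF (horizontal axis) for the measured genes of 4 lists (vertical axis), in wild type (blue) and on the arrays labelled mutant (orange). Points are estimates from 3 against 3 arrays, bars are standard errors, and filled points passed at an adjusted p under 0.05; 16 of 30 NF-kB targets passed in each genotype, all of them higher.

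On the arrays labelled mutant, TNF raised Acod1 by 5.73 on the log2 scale (53-fold, SE 0.46, 3 arrays per group) and Aoc1 by 5.51 (SE 0.22). Without TNF both genes read at most 4.58 there, near the floor, where fold changes are compressed. Gpr25 rose by 5.15 (SE 0.42), and Fpr2 and Ly6i each by 4.67 (SE 0.51 and 0.33). The actin-bundling gene Fscn1 (4.62), Cp (4.61), Adgre4 (4.60), Sema6d (4.47) and Dpysl3 (4.44) also rose. Mmp8 fell by 4.75 (SE 0.47), F13a1 by 4.31 (SE 0.48) and Ifitm6 by 4.16 (SE 0.42). Vcan (-3.75), Elane (-3.50), Ccr1 (-3.22), Mgam (-3.21), Spint1 (-3.07), Elobl (-2.82, SE 0.66) and Ncam1 (-2.82, SE 0.57) fell too. Elobl read 8.37, 8.83 and 7.88 on the untreated arrays labelled mutant and 5.43, 3.79 and 7.4 on the treated ones. On the wild-type arrays Elobl read at most 4.03, near the floor, so a fall could not be seen there. In all 446 genes rose and 338 fell (784, limma; 406 and 450 with centred arrays, 514 and 305 with cyclic loess), 340 of them by at least 2-fold, and the arrays of each group did not overlap for 26.2% of genes against 10% by chance. The count was 444 without untreated replicate 2, 457 without untreated replicate 3, 506 and 512 without treated replicates 2 and 3, and 452 with the Xist and Eif2s3y levels as covariates. Elane, Elobl and Ncam1 did not pass with the covariates (adjusted p = 0.0689, 0.16 and 0.0626), nor Elobl under a replicate block (0.0562) or without any single array but untreated wild-type replicate 1 and treated replicate 3 of the arrays labelled mutant (from 0.0531 to 0.138), Elane without untreated replicate 1, 2 or 3 or treated replicate 2 or 3 (from 0.0624 to 0.106), or Ncam1 without untreated replicate 2 or 3 (0.0748 and 0.0799).

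NF-kB targets rose in 16 of 30 cases, and in 21 when adjusted over the list alone, among them Relb by 3.49 (SE 0.12), Tnfaip3 by 3.77 (SE 0.16) and Traf1 by 3.09 (SE 0.31). Camera gave adjusted p = 4.15e-29 for the list (adjusted p = 0.000172 with an estimated correlation). Of 9 MHC class II genes 5 rose, also 5 when adjusted over the list alone, with H2-Eb1 at 2.93 (SE 0.30) and Cd74 at 2.55 (SE 0.27), and camera adjusted p = 4.97e-06 (adjusted p = 0.338 with an estimated correlation). Of 24 granulocyte markers 8 fell, and 17 when adjusted over the list alone, with Cxcr2 at -2.44 (SE 0.19) and Ltf at -2.21 (SE 0.34), and camera adjusted p = 9.62e-11 (adjusted p = 0.338 with an estimated correlation). Of 23 monocyte, macrophage and dendritic markers 6 fell and 2 rose, and 9 fell and 2 rose when adjusted over the list alone. Irf8 fell by 1.36 (SE 0.22) and Cx3cr1 rose by 2.23 (SE 0.37), with camera adjusted p = 0.0357 for that list (adjusted p = 0.823 with an estimated correlation). Of 30 interferon-stimulated genes 3 rose, Ifih1 (1.13), Oas1a (0.41) and Parp14 (0.48), and 2 fell, Ifitm3 (-0.37) and Oasl1 (-0.88), and 4 rose and 2 fell when adjusted over the list alone (camera adjusted p = 0.0357; adjusted p = 0.446 with an estimated correlation). Of 19 stromal and endothelial markers 1 fell over all genes, Pecam1 at -1.15 (SE 0.18), and 1 rose and 1 fell when adjusted over the list alone (camera adjusted p = 0.0357; adjusted p = 0.393 with an estimated correlation). None of the 15 mast cell, basophil and eosinophil markers passed in limma over all genes, and 1 rose and 2 fell when adjusted over the list alone (camera adjusted p = 0.956, fry adjusted p = 0.84, median -0.07, mean -0.08, camera direction up). fry did not call the monocyte and interferon lists (adjusted p = 0.158 for each). With the mean of probe sets the interferon, monocyte and stromal lists did not pass (adjusted p = 0.1, 0.0584 and 0.0729), nor the interferon and stromal lists with the Xist and Eif2s3y covariates (0.0592 for each). The interferon list did not pass without untreated replicate 1 or 2 or treated replicate 3 (adjusted p = 0.12, 0.118 and 0.121). The monocyte list did not pass without untreated replicate 3 (0.392), treated replicate 2 (0.157) or untreated wild-type replicate 1 or 2 (0.0646 and 0.0538). The stromal list did not pass without untreated replicate 1 or 2 (0.0843 and 0.0967), treated replicate 1 or 2 (0.0576 and 0.0964) or untreated wild-type replicate 2 (0.0507). Over all alternatives the adjusted p ran from 1.41e-31 to 0.000172 for NF-kB targets, from 9.4e-07 to 0.338 for MHC class II genes, from 3.63e-13 to 0.338 for granulocyte markers, from 0.000276 to 0.823 for the monocyte list, from 0.0062 to 0.446 for the interferon list and from 0.014 to 0.393 for the stromal list. Xist read 5.12 on untreated replicate 1 of this genotype and at least 12.04 on its other arrays, and Eif2s3y read 4.16 on untreated replicate 2.

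Of the 1146 genes called for TNF in wild type or on the arrays labelled mutant, 551 were called in both and 0 of those had opposite directions. The shared calls were 325 higher, against 12 for independent lists, and 226 lower, against 7.9. Across genes, which are not independent replicates, the log2 fold changes correlated at Pearson's r = 0.827 and Spearman's rho = 0.601. No gene passed for a difference between the TNF effects in limma (0 of 18193), while 527 had an unadjusted p under 0.05 and 910 would by chance. Array weights, a replicate block, both other scalings and the fit with trend and robust options also called 0, and leaving out untreated wild-type replicate 1 called 1, Tm4sf1 at -2.48. The 95% interval of this difference for a single gene, unadjusted, reached 0.38 to each side on the log2 scale for the median gene and 0.44 for the median of the genes called for TNF averaged over genotype. In simulated data with 100 genes changed by 1 and 100 by 2, 68% of differences of 1 passed over all genes. Such differences and smaller ones could therefore be missed, and more so where fewer genes differ. The smallest unadjusted p-values with a larger value on the arrays labelled mutant belonged to Abca1 (1.20), Slamf7 (0.68), Ahnak2 (0.96), Il4 (0.51) and Mospd4 (0.69). Those with a smaller value belonged to Gfra4 (-0.54), Spats2 (-1.29), Cbx7 (-0.72), B3gnt3 (-0.54) and Lrat (-0.48). None of these 10 passed, each with adjusted p = 1.

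**Figure D3:**
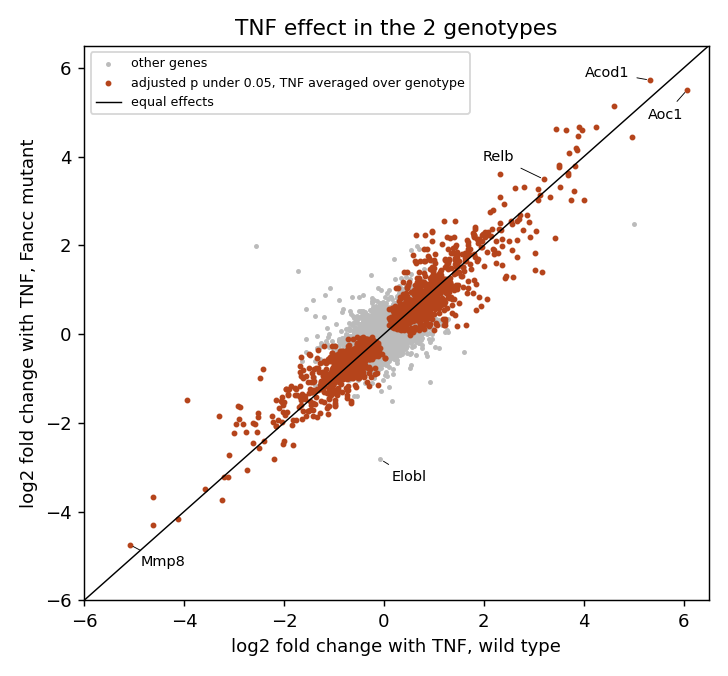
Log2 fold change with TNF in wild type (horizontal axis) against that on the arrays labelled mutant (vertical axis), 1 point per gene. Orange points are the 2207 genes called for the TNF effect averaged over genotype, and the line marks equal effects; over all genes Pearson's r was 0.827.

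Averaged over genotype, TNF changed 2207 genes in limma, 1057 higher and 1150 lower, with Aoc1 at 5.79 (SE 0.15), Acod1 at 5.53 (SE 0.33), Gpr25 at 4.87, Dpysl3 at 4.71 and Fpr2 at 4.46. Mmp8 (-4.92), F13a1 (-4.46), Chil3 (-4.15), Ifitm6 (-4.14) and Elane (-3.54) lay at the other end. Centring the arrays on their median turned the split to 852 higher and 1419 lower, and cyclic loess to 1215 higher and 979 lower. Of the 30 NF-kB targets 20 rose and 0 fell in this average, and 23 rose when adjusted over the list alone (camera adjusted p = 1.35e-26; adjusted p = 0.000242 with an estimated correlation). Of 24 granulocyte markers 19 fell, and 21 fell and 1 rose when adjusted over the list alone (camera adjusted p = 1.01e-11; adjusted p = 0.232 with an estimated correlation). Over 19 alternatives the adjusted p of these lists ran from 2.18e-28 to 0.000242 and from 9.26e-14 to 0.232. The count was 1270 with the Xist and Eif2s3y levels as covariates and 444 on only the 7 arrays with signal from both.

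Few genes passed for genotype. Without TNF the single call was 6720489N17Rik, a predicted gene named here after its value was seen, which was lower by a log2 difference of -1.18 on the arrays labelled mutant (limma adjusted p = 0.0388, 3 arrays per group without overlap). Not passing were the larger differences of Elobl (4.45, SE 0.66), Fbp1 (2.82, SE 0.42) and Cep85 (2.02, SE 0.34), and those of Ptms (0.96), Lrat (0.35), Epb41l1 (-0.49), Ube2l6 (-0.55), Ddn (-1.16), Il4 (-0.48) and Mylip (-0.57). With TNF the single call was Fbp1, fructose-1,6-bisphosphatase of gluconeogenesis, which was higher by 4.45 (21.8-fold, SE 0.42, adjusted p = 0.00886). Not passing were Cep85 (1.90), Slamf7 (0.61), Mir22hg (0.67), Ctse (3.11), Epb41l1 (-0.62), Etl4 (-1.26), Bdh2 (-1.03), Cbx7 (-0.70) and Mpzl1 (-0.74). At an unadjusted p under 0.05 there were 749 genes without TNF and 1018 with it, against 910 by chance, and the arrays did not overlap for 8.1% and 11% of genes, against 10% by chance. The 6720489N17Rik call without TNF was kept under a replicate block, with the mean of probe sets, with both other scalings and with array weights (adjusted p from 0.0175 to 0.0415). Of the fits that left out 1 array it was kept in those without untreated wild-type replicate 2, untreated replicate 1 of the arrays labelled mutant or treated wild-type replicate 2, and lost without each of the other 9 arrays. It was also lost without dim genes, with trend and robust options, with the covariates, on the 7 arrays with both Xist and Y-linked signal, and when only the 2 groups were fitted, where Elobl was called instead. Without untreated wild-type replicate 2 there were 3 calls, 6720489N17Rik, Ddn and Glyat. The Fbp1 call with TNF was lost without treated replicate 1 or 3 of the arrays labelled mutant (adjusted p = 0.0871 and 0.069), at log2 differences of 4.43 and 4.51, and when only the 2 groups were fitted, and centring the arrays gave 1 higher and 1 lower call. With TNF there were 9 calls without untreated wild-type replicate 1, 7 without treated replicate 2 of the arrays labelled mutant and 2 without treated wild-type replicate 3, Fbp1 among them each time. Untreated wild-type replicate 1 had the lowest array weight, 0.31 against 0.73 to 1.67 on the other arrays. It enters the comparison with TNF only through the shared estimate of the spread.

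Averaged over treatment 4 genes differed between genotypes in limma, while 1344 had an unadjusted p under 0.05, against 910 by chance. Fbp1 was higher on the arrays labelled mutant by 3.63 on the log2 scale (SE 0.30, adjusted p = 0.00124), reading 10.09 to 11.20 on all 6 of them and 4.56 to 8.71 on the 6 wild-type arrays. 6720489N17Rik was lower by -1.10 (SE 0.09, adjusted p = 0.00124), and its second probe set by -1.08 (SE 0.13). Cep85, a centrosomal protein gene, was higher by 1.96 (SE 0.24, adjusted p = 0.0265) at its brighter probe set and lower by -1.56 (SE 0.18, adjusted p = 0.0282 over all probe sets) at its dimmer one. The mean of both Cep85 probe sets differed by 0.20 and did not pass. Epb41l1 was lower by -0.56 (SE 0.06, adjusted p = 0.0193), while its other probe sets stood at -0.53 and 0.20. Not passing were Ptms (0.87), Elobl (3.07), Etl4 (-0.85), Bex1 (-0.90), Ube2l6 (-0.43) and Bex4 (-0.84). With the Xist and Eif2s3y levels as covariates the calls were Fbp1 (3.60) and 6720489N17Rik (-1.08), and the Cep85 and Epb41l1 calls were lost there (adjusted p = 0.0769 and 0.156), under a replicate block (0.109 and 0.0858) and with the mean of probe sets (0.771 and 0.394). Without single arrays Cep85 passed only without untreated wild-type replicate 1 (otherwise from 0.0573 to 0.114), Epb41l1 only without an untreated wild-type array (otherwise from 0.0592 to 0.0939), and centring the arrays gave 4 higher and 2 lower calls.

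**Figure D4:**
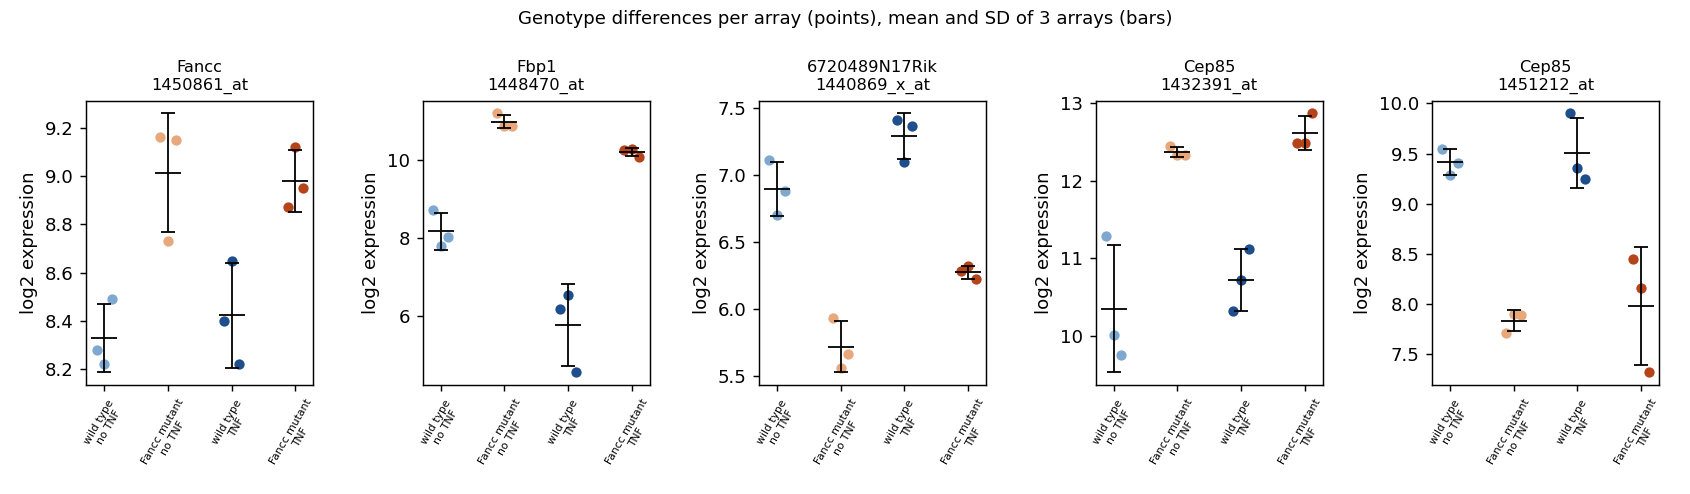
Log2 expression (vertical axes) on each of the 12 arrays for Fancc, Fbp1, 6720489N17Rik and both probe sets of Cep85, by group. Points are arrays and bars give the mean and SD of 3; the Cep85 probe sets differ by genotype in opposite directions, 1.96 and -1.56 averaged over treatment.

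Of those 4 genes, Fbp1 and 6720489N17Rik lie on chromosome 13 beside Fancc, 2 and 5 tested genes away in the order of the GRCm38.p6 annotation. The 100 tested genes on each side of Fancc held 2 calls among 200, against 2 among the 17944 other genes with a position (Fisher's exact test, two-sided, p = 0.000715). Most neighbours showed no such difference, and an unadjusted p under 0.05 was seen for 9.5% of the 200 genes against 7.4% elsewhere (Fisher's exact test, two-sided, p = 0.274). For the 30 genes on each side these were 15% and 7.4% (Fisher's exact test, two-sided, p = 0.0411). Of the 2 tested genes next to Fancc, both named here after their values were seen, Ptch1 stood at -0.11 and did not pass. The other, the aminopeptidase gene Aopep, stood at 0.17 for its brightest probe set and did not pass, while another of its probe sets differed by -0.66 (SE 0.08, adjusted p = 0.0282 over all probe sets).

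No member of any gene list passed for genotype in limma over all genes. Averaged over treatment, camera called 6 lists at its preset correlation, none of which passed with the correlation taken from the data (adjusted p = 0.537 with an estimated correlation for each), and fry called 0 lists. The 32 measured stem and early progenitor genes had a median log2 difference of -0.22, with 4 members above 0 and 7 lower when adjusted over the list alone (camera adjusted p = 2.09e-07). The homeobox gene Hoxb5 stood at -0.77 (SE 0.18), Ndn at -1.41 (SE 0.34), Fgd5 at -1.29 (SE 0.34) and Esam at -0.66 (SE 0.18). Megakaryocyte markers had a median of -0.29, with 3 of 16 lower when adjusted over the list alone (camera adjusted p = 0.00124). Monocyte, macrophage and dendritic markers had a median of 0.27 with 0 of 23 called over the list alone (adjusted p = 5.9e-06), granulocyte markers of 0.30 with 1 of 24 higher over the list alone (adjusted p = 0.000214), and MHC class II genes of 0.31 with 1 of 9 higher over the list alone (adjusted p = 0.000253). Chemokines and cytokines had a median of 0.08 with 0 of 27 called over the list alone (adjusted p = 0.0165). The chemokine and cytokine list did not pass without replicate 1 of the untreated (adjusted p = 0.0943) or treated (0.0717) wild-type arrays, or treated replicate 3 of the arrays labelled mutant (0.225), nor with the mean of probe sets (0.0505). Over 19 alternatives each list reached adjusted p = 0.537 at the highest, and the lowest lay between 7.23e-11 for the monocyte list and 0.000749 for chemokines and cytokines.

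Without TNF, camera called stem and early progenitor genes (median -0.23, adjusted p = 6.71e-05; adjusted p = 0.71 with an estimated correlation), megakaryocyte markers (-0.31, adjusted p = 6.71e-05; adjusted p = 0.416 with an estimated correlation) and mast cell, basophil and eosinophil markers (-0.30, adjusted p = 0.000341; adjusted p = 0.71 with an estimated correlation). Adjusted over the list alone 0, 1 and 3 of their members were lower, and the mast cell list did not pass without untreated wild-type replicate 2 (adjusted p = 0.229). The ranges over alternatives were 3.56e-06 to 0.71, 2.99e-07 to 0.515 and 2.43e-05 to 0.71. With TNF it called monocyte, macrophage and dendritic markers (median 0.50, adjusted p = 7.79e-07), stem and early progenitor genes (-0.23, adjusted p = 9.39e-06), MHC class II genes (0.36, adjusted p = 0.000208), granulocyte markers (0.28, adjusted p = 0.00022), B and early lymphoid markers (0.24, adjusted p = 0.00207) and Toll-like receptor genes (0.11, adjusted p = 0.0288). None of these 6 passed with the correlation taken from the data (adjusted p = 0.541 with an estimated correlation for each), and fry gave adjusted p = 0.603 for each, the highest over their alternatives. Adjusted over the list alone 2 monocyte and 4 granulocyte markers were higher and 0 members of the other 4 lists were called. The MHC class II list did not pass without treated wild-type replicate 1 (adjusted p = 0.0681), the granulocyte list without treated wild-type replicate 2 (0.06) or treated replicate 1 of the arrays labelled mutant (0.0556), or the B and early lymphoid list without treated wild-type replicate 1 (0.313) or treated replicate 2 of the arrays labelled mutant (0.117). The Toll-like receptor list did not pass without untreated wild-type replicate 1 (0.0633), treated wild-type replicate 2 or 3 (0.0583 and 0.152) or treated replicate 1 or 3 of the arrays labelled mutant (0.0883 and 0.313), nor without dim genes (0.112), with the mean of probe sets (0.0734) or with the covariates (0.226), and lost its call in 10 of 19 alternatives. Averaged over treatment, the Fanconi pathway list had a median of -0.06 over 26 genes and 1 gene, Fancc, higher when adjusted over the list alone (camera adjusted p = 0.303), and p53 targets had a median of 0.06 over 25 genes and 0 called over the list alone (adjusted p = 0.168). Xist and Eif2s3y levels differed between arrays of both genotypes, with low Xist on untreated wild-type replicates 1 (5.47) and 2 (5.06) and on 1 untreated array labelled mutant (5.12).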

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

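The tests of probe sets without a gene name were chosen only after the data were seen, while the gene list tests were planned. Camera called 3 gene lists for a difference between genotypes in the TNF effect, although no single member passed over all genes and fry called 0 of them (adjusted p = 0.887 for each). The log2 change with TNF on the arrays labelled mutant minus that in wild type had a median of 0.45 over mast cell, basophil and eosinophil markers, whose median change was -0.54 in wild type and -0.07 on the arrays labelled mutant (camera adjusted p = 1.23e-05; adjusted p = 0.657 with an estimated correlation, and from 7.39e-08 to 0.887 over its alternatives), with Epx at 2.13, Prg2 at 2.18 and Il4 at 0.51, and 2 of 15 members passed when adjusted over the list alone. Over monocyte, macrophage and dendritic markers the same difference had a median of 0.42, with median changes of -0.89 and -0.32 (camera adjusted p = 0.0284; adjusted p = 0.872 with an estimated correlation, and from 9.24e-08 to 0.887 over its alternatives), with Itgax at 0.62 and Siglech at 0.77, and 0 of 23 passed when adjusted over the list alone. It did not pass without untreated wild-type replicate 2 or 3 (adjusted p = 0.119 and 0.431), treated wild-type replicate 2 (0.0887), or untreated replicate 1 or 2 (0.432 and 0.206) or treated replicate 1 or 3 (0.091 and 0.702) of the arrays labelled mutant. Over B and early lymphoid markers it had a median of 0.23, with median changes of -0.16 and -0.05 (camera adjusted p = 0.0416; adjusted p = 0.796 with an estimated correlation, and from 0.000422 to 0.887 over its alternatives), with Bank1 at 1.13 and Blnk at 0.89, and 0 of 17 passed when adjusted over the list alone. It did not pass without untreated wild-type replicate 2 (0.286), treated wild-type replicate 1 (0.481), or untreated replicate 1 (0.15) or treated replicate 2 or 3 (0.18 and 0.229) of the arrays labelled mutant, nor without dim genes (0.0769).

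Signals also appeared among the 9160 tested probe sets that have no gene name here and entered no comparison of genes. Averaged over genotype, 407 of them changed with TNF. Averaged over treatment, 5 differed between genotypes. The largest of these differences was 3.28, higher on the log2 scale on the arrays labelled mutant (SE 0.20, adjusted p = 0.00034), reading 11.72 to 12.75 on those 6 arrays and 8.31 to 9.22 on the 6 wild-type arrays. The next stood 2.65 higher (SE 0.18, adjusted p = 0.00035), reading 12.48 to 13.15 against 9.47 to 10.51.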

How the results depend on the processing

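The fits on all probe sets, with the Xist and Eif2s3y levels as covariates, and on the 7 arrays with both signals were chosen only after the data were seen. Over the named genes, apart from the Fancc levels given below, 1365 of 1440 refits kept direction and side of the threshold, 60 lost a call, 15 gained 1 and 0 reversed. Of refits of called lists, 194 kept and 64 lost the call over the settings, and 400 kept and 44 lost it without an array. The lost gene calls belonged to Chil3, Elane, Elobl, Ncam1, Fbp1, Cep85 and Epb41l1. For TNF in wild type (913) there were 523 when only the 2 groups were fitted (468 of them among the 913), 384 at 2-fold or more, 410 with the covariates (373 shared) and 39 on the 7 arrays (36 shared), and leaving out an array gave 474 to 957. On the arrays labelled mutant (784) there were 340 at 2-fold or more, 452 with the covariates and 59 on the 7 arrays, and leaving out an array gave 444 to 951. Averaged over genotype (2207) there were 3337 of all probe sets, 1270 with the covariates, 444 on the 7 arrays and 458 at 2-fold or more, and leaving out an array gave 1598 to 2225. The 7 arrays leave 1 array in each untreated group, whose lone value is assumed to vary like the other groups, so fewer arrays lower those counts; the other causes were not tested, except for the covariates. For genotype without TNF (1) there were 0 without dim genes, 0 with trend and robust options, 0 with the covariates, 0 on the 7 arrays, 2 with array weights and 3 of all probe sets, and 0 to 3 without an array; a count of 1 was Elobl when only the 2 groups were fitted and without treated replicate 2 or 3 of the arrays labelled mutant, Cep85 without untreated wild-type replicate 1, and Fbp1 without treated wild-type replicate 3. For genotype with TNF (1) there were 0 when only the 2 groups were fitted, 2 with centred arrays, 3 with the mean of probe sets, 3 of all probe sets and 9 with array weights, and 0 to 9 without an array, with 9 without untreated wild-type replicate 1 7 without treated replicate 2 of the arrays labelled mutant and 2 without treated wild-type replicate 3. Averaged over treatment (4) there were 2 with the mean of probe sets, 2 with the covariates, 1 on the 7 arrays and 12 of all probe sets, and 2 to 6 without an array. The interaction gave 0 to 1 without an array, and 0 otherwise. The causes of these genotype changes were not tested.

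Replicate numbers were not treated as pairing samples in the main fit, which was fixed before the data were examined. Of same-number pairs, 7 of 18 correlated over 0.1 in their deviations (median 0.046, range -0.159 to 0.278). Of the other pairs, 6 of 36 did (median -0.024). Since 10 of 12 arrays correlated best with their own number, a link between arrays of the same number cannot be excluded. With a replicate block the counts were 920 and 790 for TNF in each genotype, 2181 on average, 1 for genotype without TNF, 3 with TNF, 3 on average, and 0 for the interaction, and 5 lists for genotype without TNF. Camera called 7 lists for TNF in wild type (1 with an estimated correlation, 11 with fry, 6 to 8 without an array), 6 on the arrays labelled mutant (1, 8, 4 to 6, and 3 with the mean of probe sets), 6 on average (1, 12, 5 to 7), 3 for genotype without TNF (0, 0, 2 to 7, and 6 without dim genes), 6 with TNF (0, 0, 5 to 8), 6 on average (0, 0, 5 to 8) and 3 for the interaction (0, 0, 1 to 6); the cause was not tested. NF-kB targets passed in all 19 alternatives for TNF in each genotype (adjusted p up to 0.000305 and 0.000172). Granulocyte and MHC class II lists lost their TNF calls with an estimated correlation alone (1 of 19 alternatives in each genotype). The correlation of TNF effects (0.827) was 0.902 without dim genes and 0.776 to 0.827 without an array, judged against an SD of 0.0149 over those fits. The small TNF change of Fancc was -0.02 without treated wild-type replicate 2 (range -0.02 to 0.195), and 0.044, 0.039 and 0.028 without untreated replicates 1 and 3 and treated replicate 1 of the arrays labelled mutant (range -0.17 to 0.044). The enrichment of genotype calls beside Fancc had p = 6.42e-05 for 30 genes on each side and p = 0.00856 for the whole chromosome (Fisher's exact test). No scaling moved the median of all genes by over 0.1. The number of arrays limits what could be called.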

Other observations

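The tests of the Xist and Eif2s3y covariates, of probe sets and of the position of genotype calls as an explanation were chosen only after the results were seen; the gene lists and the splits of the arrays were planned. Cytokine genes moved both ways with TNF. In wild type 6 of 27 chemokine and cytokine genes rose and 5 fell (camera adjusted p = 0.735, median -0.05, mean 0.23), on the arrays labelled mutant 5 rose and 3 fell (adjusted p = 0.451), and in each genotype 8 rose and 6 fell when adjusted over the list alone. The lymphotoxin gene Ltb rose by 3.69 and 3.64, the acute phase gene Saa3 by 2.34 in each genotype and Cxcl16 by 1.72 and 1.58, while Il15 (-1.93 and -1.38) and Il10 (-1.05 and -1.21) fell. Cxcl10 rose by 2.45 in wild type and stood at 1.32 on the arrays labelled mutant, a difference that did not pass (-1.13, adjusted p = 1). Among cell death genes the receptor Fas rose by 2.36 and 1.99, while the promoters Casp6 (-0.61 and -0.72), Mlkl and Bid and the inhibitors Bcl2 (-1.03 and -0.95), Pim1 and Pim2 (-1.24 and -1.06) fell in each genotype. The p53 target Pmaip1 rose by 1.35 and 1.11 and Cdkn1a (-0.96 and -0.92), a cell cycle inhibitor counted among the p53 targets, fell. The NADPH oxidase genes Cybb (1.86 and 2.16) and Cyba (0.96 and 0.89) rose.

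Of 32 stem and progenitor genes, Hoxa10 (1.06) rose in wild type and Procr (1.67) on the arrays labelled mutant. Neither of these, nor any other gene, passed for a difference between the TNF effects of the genotypes. Averaged over genotype 3 of the 32 rose and 2 fell, and 6 rose and 3 fell when adjusted over the list alone (camera adjusted p = 0.0678). Among cell cycle genes Nusap1 (0.38 and 0.40) rose in each genotype and Tk1 (0.31) on the arrays labelled mutant. In limma 0 of 26 Fanconi pathway genes, 0 of 24 oxidative phosphorylation genes, 0 of 18 ribosomal protein genes, 0 of 15 cholesterol synthesis genes, 0 of 12 genes of the list of cell cycle inhibitors and quiescence, which does not hold Cdkn1a, and 0 of 11 heat shock genes passed in either genotype over all genes. Adjusted over the list alone these counts were also 0, and fry called the oxidative phosphorylation list (adjusted p = 0.00848 and 0.00754, median -0.07 and -0.06). It also called genes promoting cell death (adjusted p = 0.0158 and 0.0111), genes inhibiting it (0.00251 and 0.00793), glycolysis genes in wild type (0.0254) and unfolded protein response genes on the arrays labelled mutant (0.00754, 0 of 22 called in limma, camera adjusted p = 0.0806). The aldehyde dehydrogenase gene Aldh1a1 rose by 3.42 (SE 0.52) in wild type and 2.16 on the arrays labelled mutant. Among lymphoid markers Rag1 (1.98 and 2.27), Thy1 (2.31 and 2.36) and Cd5 (1.78 and 2.28) were higher and Nkg7 (-1.65 and -1.60) was lower. Most lymphoid markers did not pass, 15 of 17 B and early lymphoid and 14 of 18 T and NK markers in wild type. On the arrays labelled mutant 16 of 17 and 14 of 18 did not pass. Car2 rose by 0.97 and 0.96 and Klf1 (-0.66 and -0.65) fell among erythroid markers, and the integrin gene Itgb3 rose by 1.29 and 1.61 among megakaryocyte markers. Dusp1 rose by 0.97 and 0.87 and Fosl1 (-1.38 and -1.57) fell among immediate early genes. Tirap (-0.96 and -0.80) fell among Toll-like receptor genes and adaptors, and H2-K1 rose by 0.30 and 0.38 among MHC class I genes. Pfkp (-0.82) was the only glycolysis gene called, in wild type. Of the lists of these 2 paragraphs camera called only unfolded protein response genes in wild type (adjusted p = 0.0236). With an estimated correlation camera gave adjusted p = 0.208 for that list, and its call was also lost without untreated replicate 3 or treated replicate 1. The lists not called had camera adjusted p from 0.0805 to 0.987 in wild type and from 0.0806 to 0.92 on the arrays labelled mutant. In wild type median and mean had opposite signs for aldehyde (-0.07 and 0.19), p53 (-0.01 and 0.03), immediate early (-0.11 and 0.03), erythroid (-0.11 and 0.02), T and NK (-0.13 and 0.04), Toll-like receptor (0.03 and -0.01) and Fanconi (0.02 and -0.01) lists. On the arrays labelled mutant this held for aldehyde (-0.02 and 0.14), oxidative stress (-0.01 and 0.03), immediate early (-0.09 and 0.14), erythroid (-0.06 and 0.07), B lymphoid (-0.05 and 0.23) and Fanconi (0.01 and -0.02) lists, while megakaryocyte (-0.15 and -0.01) and MHC class I (-0.02 and -0.04) lists had camera direction up.

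Of the 4 genotype calls 2, Fbp1 and 6720489N17Rik, lay beside Fancc on chromosome 13, while Cep85 lies on chromosome 4 and Epb41l1 on chromosome 2. The 200 genes around Fancc held more calls than an even spread over the genome would give (Fisher's exact p = 0.000715). Over the 200 genes this excess rests on those 2 calls, since an unadjusted p under 0.05 was seen for 9.5% of them and 7.4% of the other genes (Fisher's exact p = 0.274). For the 30 genes on each side, which include those 2 calls, the shares were 15% and 7.4% (Fisher's exact p = 0.0411). So few calls cannot exclude an effect of Fancc loss with no local component as the cause. The values argue against sex composition as the cause. With the Xist and Eif2s3y levels as covariates at least 98% of the Fbp1 and 6720489N17Rik differences was kept (3.60 with a 95% interval of 0.57 to each side, and -1.08 with 0.22). Calls favour genes with a small spread within groups, from which the effect of the covariates is estimated. On the untreated arrays with low Xist, Fbp1 read 8.71 and 7.79 in wild type and 11.2 on the array labelled mutant. There 6720489N17Rik read 7.11 and 6.7 against 5.93. For Fbp1, which has a single probe set, a strain variant under the probes cannot be told apart from a difference in transcript level. Both probe sets of 6720489N17Rik moved alike (-1.10 and -1.08). That argues against such a variant for this gene, unless it lies under both. DNA from another strain carried along with the targeted allele may explain both genes, a hypothesis found and examined on the same arrays and not tested by genotyping.

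The Cep85 probe sets moved in opposite directions by genotype, the brighter by 1.96 (SE 0.24) and the dimmer by -1.56 (SE 0.18). With the Xist and Eif2s3y covariates the differences were 2.06 (SE 0.23, 95% interval 0.53 to each side) and -1.58 (SE 0.20, 0.46 to each side). At least 101.8% of their size was kept, which argues against sex composition as their cause, within the limit given above for calls. On the untreated arrays with low Xist the brighter probe set read 11.29 and 10.01 in wild type and 12.45 on the array labelled mutant. The dimmer one read 9.55 and 9.29 against 7.71. The gene's call ended with the covariates (limma adjusted p = 0.0769 against 0.0265, and 0.000563 to 0.771 over the alternatives) because the degrees of freedom fell from 10.75 to 8.6 and the unadjusted p rose from 5.83e-06 to 1.27e-05, while the SE went from 0.238 to 0.231. A change in transcript form or a sequence difference between the mice of the 2 genotypes could each give such values, and neither was tested.

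Xist was low on 3 untreated arrays and Eif2s3y on 1 untreated and 1 treated array, so sex composition overlapped with treatment. Over 2125 called autosomal genes the changes with the covariates followed those without at a slope of 1.031 and 100% kept their sign. The called changes thus did not shrink with these levels. Calls favour genes with a small spread within groups, from which the effect of the covariates is estimated. The slope was taken only for the average over genotype. With the covariates 100% of the genes called in wild type and of those called on the arrays labelled mutant also kept their direction. Averaged over genotype, 1114 of the 2207 genes still passed in limma with the covariates. For those genes this argues against sex composition, as far as these 2 levels measure it, as the cause. Sex composition was not excluded for the other called genes. The count fell from 2207 to 1270 while the median SE rose from 0.10 to 0.128 and the degrees of freedom fell from 10.75 to 8.6. The median size of the change went from 0.539 to 0.548. The shares of these 2 in the fall were not separated, larger errors and fewer degrees of freedom. RMA had already equalised the arrays, so an overall shift that it removed cannot be seen in these values. TNF is the difference the design names. The list of NF-kB targets, fixed before the data were examined, passed in all 19 alternatives in each genotype, and these values go with an effect of TNF. For single called genes such an effect was examined only on the same arrays.

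Other splits of the arrays were compared with the real one. For TNF averaged over genotype (2207 genes) 1 of 100 splits, the real one, gave as many, the highest other gave 4, and chance can be excluded. For genotype averaged over treatment (4 genes) 2 of 100 gave as many, the highest other also 4. Another grouping of the arrays thus reached the whole count, and only 100 of 200 possible splits were run, so chance cannot be excluded for it. For the interaction the count was 0, so all 100 splits gave at least as many by construction (highest other 4), which decides nothing about chance. The 10 splits of 6 arrays are too few for TNF in wild type (913 genes, highest other 0, 1 split as large), TNF on the arrays labelled mutant (784, 0, 1), genotype without TNF (1, 1, 2) and genotype with TNF (1, 2, 3).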
